A study of Mus musculus with 6 samples.

How the data were processed

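RNA from 6 samples of mouse 3T3-L1 adipocytes was profiled, 3 untreated and 3 treated with 0.125 μg/mL Smilax glabra flavonoids, all 8 days after differentiation. Per the labels' protocols, total RNA was extracted with TRIzol, libraries were made with a TruSeq RNA kit and sequencing was on an Illumina HiSeq. The authors deposited 1 table of FPKM values, with 46095 gene symbols and 1 column per sample, and no column was left unused. Per the submitters' processing notes, reads were checked with FastQC and aligned with HISAT2 to the mouse build mm10, and no versions are named. The tool that counted fragments, the annotation and the use of strand are not given in the sources used here. Reads of paralogs, pseudogenes and overlapping or antisense genes therefore cannot be assigned with certainty.

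Although the table holds no counts, each gene's FPKM values are whole multiples of the value of 1 fragment. The relative depths of the libraries were taken from the commonest ratio of those steps between libraries, and whole fragments were then solved for each gene. All values of the 22235 genes above 0 came out whole within a tolerance of 0.005 fragments. The totals were 21952064, 23237722 and 25083868 for untreated replicates 1, 2 and 3 and 24871930, 26355863 and 24621562 for flavonoids replicates 1, 2 and 3. Where all of a gene's fragment numbers share a divisor, the solution is too small by that divisor. On simulated fragments 98.2% of numbers were exact and 100% were right up to such a divisor. The gene length implied by each step had a Spearman rho of 0.809 across 10891 genes with the annotated exon length, where genes are not independent replicates. The fragment numbers speak to counting error only and not to the spread between samples.

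Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend in the empirical Bayes step, for the 11464 genes with a mean of at least 1 FPKM over the 6 samples. No further scaling and no covariate was used. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Changes of at least 2-fold mean a fitted change of at least 1 on the log2 scale. An exact permutation test of 3 samples against 3 cannot give a p below 0.1 and was not used. The tests, groups, 40 gene lists, the rule for named genes and the first set of other settings below were fixed before the data were examined. Of the lists, 34 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes. Adjustment was over the 34 lists.

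The named genes are the 10 higher and 10 lower genes of largest fitted change among those past the threshold with a mean of at least 5 FPKM in the higher group and no overlap between groups, leaving out unnamed gene models. To these were added the 3 called members of smallest p in each list and a panel of 25 adipocyte genes printed whatever their result. Not every gene the rule takes is described in the text. Gene positions come from GENCODE release M21 on GRCm38, the assembly that mm10 denotes. Agpat9, Ctgf, Cyr61, Wisp2 and TrnW had no entry of that symbol there and are given without positions.

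Replicates were compared first. Chi-square per degree of freedom between libraries of 1 group ranged from 6.12 to 112, so no library was a copy of another. Correlations of log2 values were 0.967 to 0.989 within untreated, 0.987 to 0.995 within treated and 0.955 to 0.981 between groups. The labels place all libraries on 1 sequencing lane and name no batch. The script was tested on 20 sets of simulated data with the real means, depths and the median dispersion within groups over 11464 genes. It recovered 6.2%, 58.2%, 98.0% and 99.6% of genes changed 1.25-fold, 1.5-fold, 2-fold and 4-fold, and 9.53% of its calls were unchanged genes. Every simulated gene had the same dispersion and no trend over gene length. With a length slope added to the libraries of a simulated set there were 82 calls, and 155 after its removal.

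Other settings fixed beforehand were the replicate number as a block, pseudocounts of 0.1 and 5, no filter and a minimum mean of 5 FPKM, rescaling to TPM, median-ratio scaling, quantile normalization, variance estimates without trend or robust to outliers, leaving out each library, and the other list tests. Chosen after seeing the data were the removal of each library's smooth trend over implied gene length (loess, span 0.5), alone, with the block and with each library left out, and limma's voom on the recovered fragments. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the recovery of fragments, the sequence checks and the figures.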

Results

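The series measured messenger RNA in 3T3-L1 adipocytes, cells of a mouse embryonic fibroblast line that can be driven to store fat in culture. All cells were taken 8 days after differentiation. One group of 3 samples was left untreated and the other group of 3 received 0.125 μg/mL of flavonoids from Smilax glabra, a climbing plant whose rhizome is used in herbal medicine. The comparison asks which transcripts differ between treated and untreated cells labelled adipocytes. Of 25 listed genes of mature adipocytes, 12 had a mean under 1 FPKM, with Adipoq, Plin1, Cd36 and Slc2a4 among them. How far the cells had matured therefore stays open. The deposited values are FPKM, fragment counts scaled by transcript length and library depth, for 46095 genes, of which 22235 were above 0 in at least 1 sample. Whole fragments could be worked back from the steps between values, and their totals ran from 21952064 to 26355863 per library. Nothing in the labels says whether the 3 samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

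Flavonoid-treated cells had higher levels of stress-response transcription factors and their targets, of the lipid droplet protein Plin2 and of the pantetheinases Vnn1 and Vnn3. They had lower levels of part of the hypoxia-inducible, glycolytic, interferon-stimulated and cell cycle genes tested. As lists, the stress lists and these 4 were called by camera and fry, but no list call was kept with an estimated correlation (lowest adjusted p = 0.178). Of 11464 genes with a mean of at least 1 FPKM, 557 were higher and 588 lower with flavonoids (limma on log2(FPKM + 1), Benjamini-Hochberg adjusted p under 0.05). At least 2-fold changes on that scale were found for 56 higher and 117 lower genes. In all 1145 called genes the 3 treated values lay on one side of the 3 untreated values. With 3 samples per group a called gene is nearly bound to separate in this way, so this adds no support. Such separation was seen in 34.3% of tested genes, where 10% is the chance for any gene taken alone. Genes vary together, so the share in a single division can lie far from 10%. Fold changes on the log2(FPKM + 1) scale understate the change of weakly expressed genes.

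Among the genes chosen by size, Cox6a2, a heart and muscle isoform of a cytochrome c oxidase subunit, rose from 4.30 ± 1.80 to 20.2 ± 3.44 FPKM (SD, n = 3 per group; log2 change 2.04, SE 0.23, limma adjusted p = 0.00328). It lies on chromosome 7 at 128205435 to 128206387 (GRCm38, as are all positions given). Ostn, which encodes the secreted peptide osteocrin, rose by a log2 change of 1.76, from 1.73 ± 0.417 to 8.27 ± 1.45 FPKM. The neighbouring genes Vnn3 (chromosome 10, 23851462 to 23869843) and Vnn1 (23894688 to 23905343) rose 3.49-fold and 3.19-fold in mean FPKM. Angptl6, an angiopoietin-like secreted protein, rose 3.20-fold, and Mmp11, a matrix metalloproteinase, rose from 72.4 ± 7.47 to 206 ± 14 FPKM. Slc6a9, a glycine transporter, rose 2.95-fold. Agpat9, an older symbol of the glycerol-3-phosphate acyltransferase gene Gpat3, rose 4.02-fold from 1.27 ± 0.00891 FPKM. The stress genes Ddit3 and Trib3 complete the 10 largest increases.

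The 10 largest decreases were led by Spon2, a secreted matrix protein on chromosome 5 at 33198184 to 33218455, which fell from 21.5 ± 0.487 to 5.52 ± 0.880 FPKM (SD, n = 3 per group; log2 change -1.79, SE 0.13, limma adjusted p = 0.00155). The small leucine-rich proteoglycan genes Lum and Fmod fell by 1.77 and 1.73 on the log2 scale, Fmod from 257 ± 69.1 to 75.3 ± 11 FPKM. Wt1, a zinc-finger transcription factor, went from 6.58 ± 0.565 to 1.40 ± 0.118 FPKM. Cda, the cytidine deaminase gene, fell by 1.59 and Cnih2 by 1.55 on the log2 scale. Ahr, the aryl hydrocarbon receptor that binds many plant aromatic compounds (chromosome 12, 35497974 to 35535038), went from 8.91 ± 2.16 to 2.48 ± 0.704 FPKM. Egln3 and Ifi27l2a are described with their groups. TrnW, named like the mitochondrial tryptophan transfer RNA gene, also met the rule, with 8.71 ± 1.40 and 2.55 ± 2.50 FPKM, but so short an RNA is poorly sampled by such libraries. Outside the rule, and chosen after its values were seen, the unnamed gene model 2610528A11Rik fell by 3.73 on the log2 scale, from 20.4 ± 6.37 to 0.582 ± 0.327 FPKM.

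**Figure D1:**
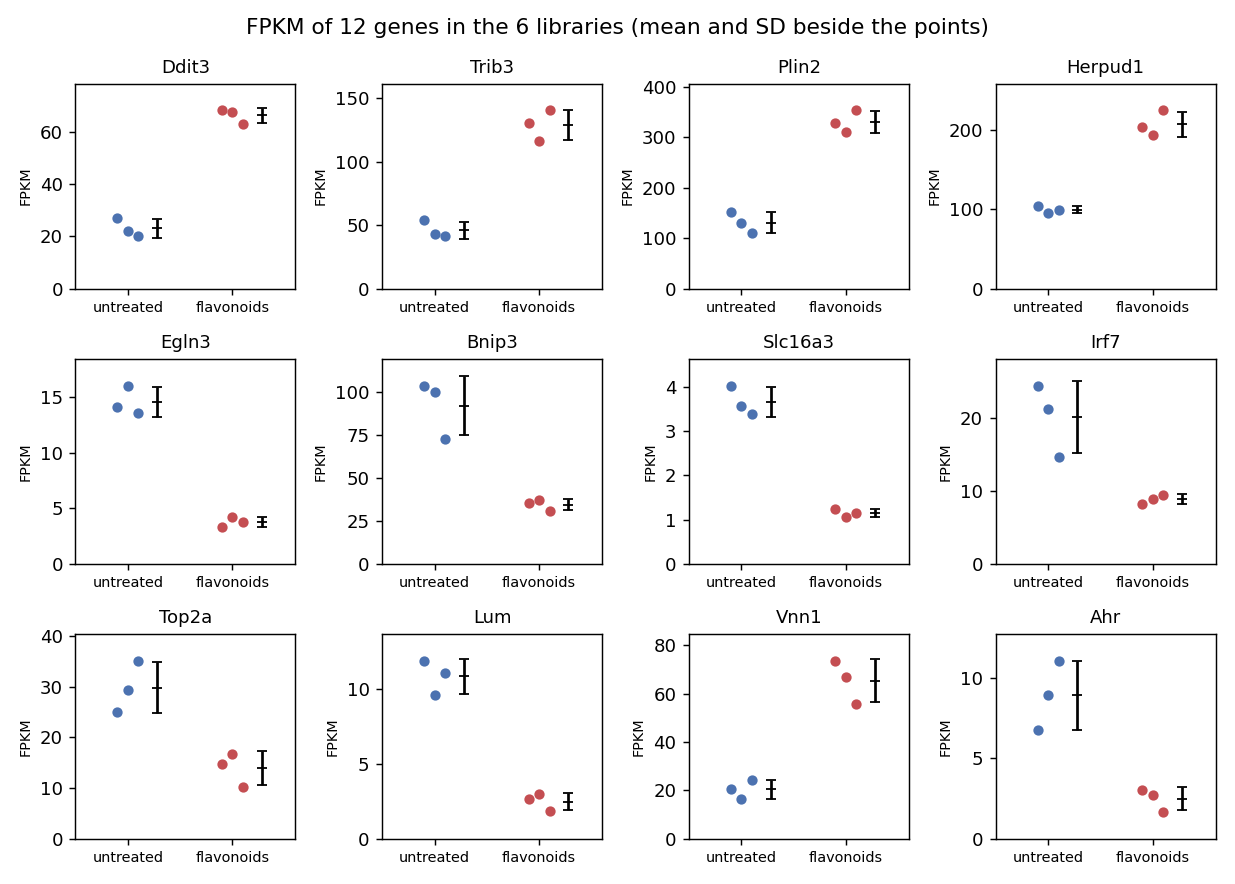
FPKM (vertical axes, each starting at 0) of 12 named genes in the 3 untreated (blue) and 3 flavonoid-treated (red) libraries, with the group mean and SD beside the points. In each panel the treated libraries lie on one side of the untreated ones, for example Ddit3 at 66.4 ± 2.89 against 23.1 ± 3.71 FPKM and Egln3 at 3.76 ± 0.421 against 14.6 ± 1.32 FPKM.

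Genes of the ATF4 integrated stress response, which are induced when amino acids are short or protein folding fails, were higher with flavonoids. Of 24 tested members 17 rose and 0 fell (18 rose when adjusted over the list alone), with a median log2 change of 0.86. Ddit3, the transcription factor CHOP (chromosome 10, 127290774 to 127296288), rose 2.87-fold from 23.1 ± 3.71 to 66.4 ± 2.89 FPKM (n = 3 per group, limma adjusted p = 0.0018). Trib3, a pseudokinase induced by ATF4, rose 2.80-fold, and Chac1, which degrades glutathione, rose 2.03-fold. Atf4 itself went from 553 ± 112 to 875 ± 23.9 FPKM (log2 change 0.68). The list had an adjusted p of 4.06e-13 in camera with the preset correlation, 0.00308 in fry, and adjusted p = 0.178 with an estimated correlation. In the endoplasmic reticulum stress list, 8 of 20 members rose and 0 fell (10 rose adjusted over the list alone). Herpud1, part of the degradation machinery for misfolded proteins, rose 2.08-fold, the chaperone gene Hyou1 rose 2.35-fold and Manf rose 1.63-fold. That list had adjusted p = 3.6e-07 in camera, 0.0083 in fry and adjusted p = 0.178 with an estimated correlation.

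Hypoxia-inducible genes were lower with flavonoids, with 14 of 22 tested members down and 1 up (15 down and 1 up adjusted over the list alone) and a median log2 change of -0.68. Egln3, an oxygen-sensing prolyl hydroxylase on chromosome 12 at 54178981 to 54203860, was 3.88-fold lower, at 14.6 ± 1.32 against 3.76 ± 0.421 FPKM (n = 3 per group, limma adjusted p = 0.00155). Bnip3, a mitophagy receptor, was 2.68-fold lower, and Pdk1, a kinase that restrains pyruvate dehydrogenase, was 2.01-fold lower. Hk2, a hexokinase gene, was the member that rose (log2 change 0.60). The list had adjusted p = 2.95e-08 in camera, 0.00308 in fry and adjusted p = 0.178 with an estimated correlation. In the glycolysis list, which shares some of these genes, 9 of 19 members fell and 1 rose (12 fell and 1 rose adjusted over the list alone). The lactate transporter gene Slc16a3 was 3.20-fold lower, Aldoc fell by 0.96 and Eno2 by 0.61 on the log2 scale. Its adjusted p was 1.76e-05 in camera, 0.0083 in fry and adjusted p = 0.228 with an estimated correlation.

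Type I interferon response genes were lower, with 11 of 20 tested members down and 0 up (16 down adjusted over the list alone). All 20 had a negative estimate, with a median log2 change of -0.80. Ifi27l2a fell from 71.9 ± 24.5 to 21.2 ± 1.48 FPKM (n = 3 per group, limma adjusted p = 0.00546), although it belongs to a family of close copies that may share reads. The transcription factor gene Irf7 was 2.28-fold lower and Oasl2 fell by 0.82 on the log2 scale. The list had adjusted p = 1.77e-09 in camera, 0.0172 in fry and adjusted p = 0.242 with an estimated correlation. Cell cycle genes were lower too, with 12 of 34 members down and 0 up (20 down adjusted over the list alone). Ccnd1, which encodes cyclin D1, was 1.62-fold lower, the mitotic kinase gene Aurkb 1.66-fold lower and the topoisomerase gene Top2a 2.14-fold lower. That list had adjusted p = 2.1e-07 in camera, 0.0118 in fry and adjusted p = 0.242 with an estimated correlation.

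**Figure D2:**
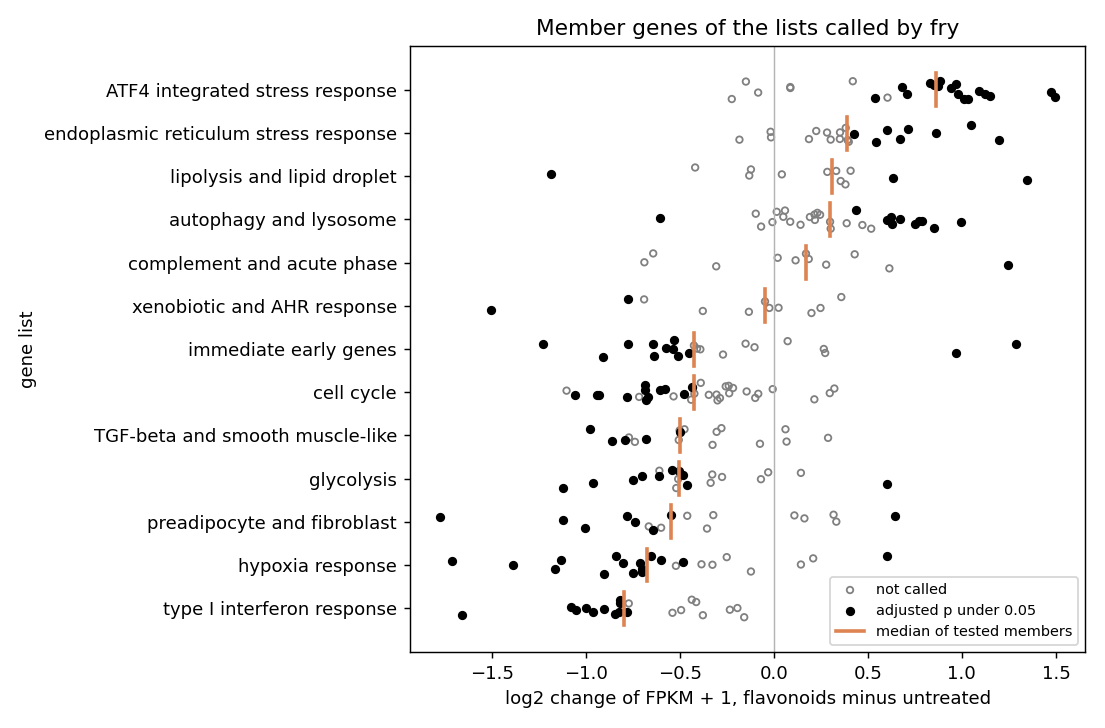
Log2 change of FPKM + 1, flavonoids minus untreated (horizontal axis), of every tested member of the 13 lists called by fry, with filled points for genes at adjusted p under 0.05, open points for the others and a bar at the list median. The ATF4 list has its median at 0.86 and the interferon list at -0.80.

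Many genes of the mature adipocyte programme were too low to be tested. Of 25 listed members, 13 reached a mean of 1 FPKM and 1 of them was called, the early adipogenic factor Cebpb, which rose 1.52-fold (limma adjusted p = 0.0271). Over all tested genes 9.99% were called, so 1 of 13 is near the general share. The list had adjusted p = 0.0954 in camera, 0.0689 in fry and adjusted p = 0.398 with an estimated correlation, and 1 member rose adjusted over the list alone. Without a filter on low values camera called it higher (adjusted p = 0.009, within a range of 0.009 to 0.163 over all alternatives). The adipogenic regulator Pparg measured 10.8 ± 1.26 and 11.6 ± 0.80 FPKM in untreated and treated cells (SD, n = 3 per group; limma adjusted p = 0.669), and Cebpa 7.18 ± 0.608 and 5.82 ± 0.272 FPKM. Fabp4, the fatty acid carrier of adipocytes, measured 219 ± 38.1 and 170 ± 22.5 FPKM, and Lpl, lipoprotein lipase, 163 ± 25.3 and 262 ± 73.0 FPKM. Adipoq, Plin1, Cd36, Slc2a4, Lep and Ucp1 of the panel stayed below 1 FPKM in all 6 libraries. Adipoq, which encodes adiponectin, lay between 0.0321 and 0.735 FPKM over the 6 libraries, and Plin1 between 0.0902 and 0.362 FPKM. Cd36 and the insulin-responsive glucose transporter gene Slc2a4 were listed at 0 in all libraries but 1, Lep reached at most 0.0603 FPKM, and Ucp1 was listed at 0 in all 6. Rps28, which every cell uses, is also listed at 0, but it lies in a stretch of chromosome 17 that was almost empty in this table. Of the 20 neighbouring protein-coding genes, 20% reached 1 FPKM around Rps28, against 40% around Cd36 and 55% around Slc2a4. A 0 taken alone is still not proof of absence.

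**Figure D3:**
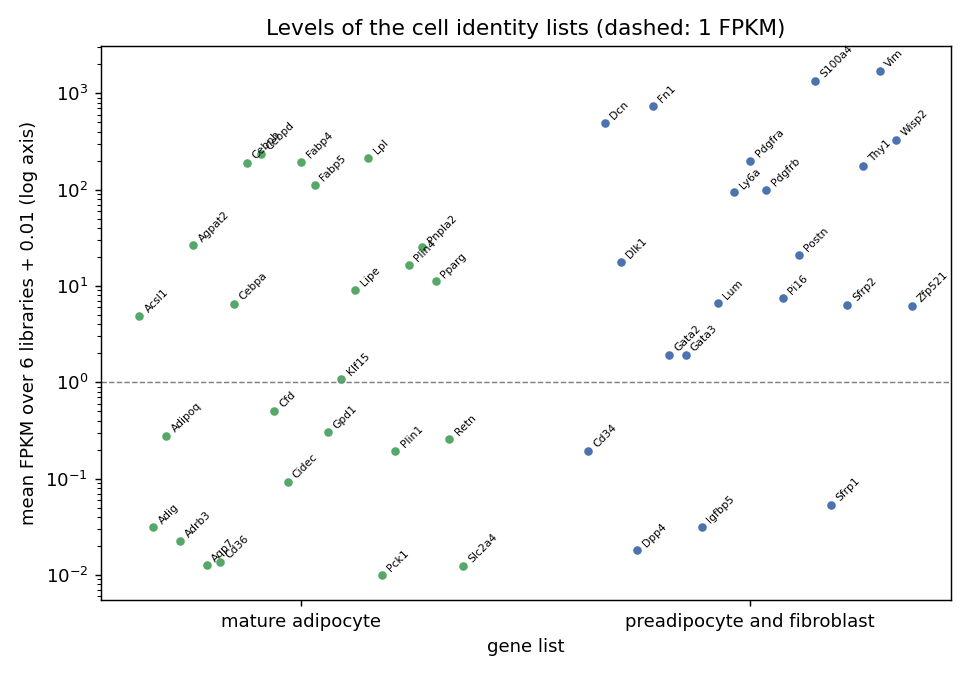
Mean FPKM over the 6 libraries plus 0.01 (log vertical axis) of each member of the mature adipocyte list (green) and of the preadipocyte and fibroblast list (blue), with a dashed line at 1 FPKM. Of the adipocyte members 12 of 25 lie under the line, against 4 of 21 fibroblast members.

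Of the preadipocyte and fibroblast list, 7 of 17 tested members fell and 1 rose (10 fell and 1 rose adjusted over the list alone). Lum fell from 10.8 ± 1.17 to 2.49 ± 0.590 FPKM (n = 3 per group, limma adjusted p = 0.0018), the Wnt modulator gene Sfrp2 was 2.27-fold lower and Thy1 1.56-fold lower, while Pi16 rose. Dlk1, a classical preadipocyte marker, measured 21.8 ± 5.62 and 13.4 ± 3.37 FPKM (adjusted p = 0.0871). The list had adjusted p = 0.00247 in camera, 0.00308 in fry and adjusted p = 0.178 with an estimated correlation. The TGF-beta and smooth muscle-like list had 5 of 17 members down and 0 up (10 down adjusted over the list alone). Cyr61 was 1.73-fold lower and Tgfb3 1.63-fold lower. It had adjusted p = 0.000126 in camera, 0.00308 in fry and adjusted p = 0.178 with an estimated correlation. Of the collagen and matrix list, 5 of 32 members fell and 1 rose (8 and 2 adjusted over the list alone). The collagen crosslinking enzyme gene Lox fell from 1133 ± 204 to 459 ± 88.1 FPKM, and Mmp2 rose 1.84-fold. That list had adjusted p = 0.0108 in camera, 0.166 in fry and adjusted p = 0.669 with an estimated correlation, and camera lost it without untreated replicate 3 (0.178) or flavonoids replicate 2 (0.0561), within a range of 0.000379 to 0.178 over all alternatives.

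Among lipid genes, Plin2, which coats lipid droplets (chromosome 4, 86648386 to 86670060), rose from 131 ± 21.1 to 331 ± 22 FPKM (n = 3 per group, limma adjusted p = 0.0029), and Abhd5, an activator of lipolysis, rose 1.6-fold. G0s2, an inhibitor of the same step, fell by 1.19 on the log2 scale. The lipolysis and lipid droplet list had 2 of 12 tested members up and 1 down (3 and 2 adjusted over the list alone), with adjusted p = 0.0954 in camera, 0.0119 in fry and adjusted p = 0.347 with an estimated correlation. At a mean of at least 5 FPKM camera called it higher (adjusted p = 0.0369, within a range of 0.0369 to 0.249 over all alternatives). Of the triacylglycerol synthesis list, Agpat9 and Agpat3 rose among 13 (3 up adjusted over the list alone), with adjusted p = 0.0413 in camera, 0.055 in fry and adjusted p = 0.442 with an estimated correlation. That camera call was lost without untreated replicate 1 (0.227), untreated replicate 2 (0.0647) or flavonoids replicate 1 (0.0761), and with all libraries on the TPM scale (0.055) or with the replicate block (0.0525), within a range of 0.00434 to 0.227 over all alternatives. Of 17 fatty acid synthesis genes, Elovl1 and Hsd17b12 rose and Acss2 fell (3 up and 1 down adjusted over the list alone; adjusted p = 0.0954 in camera). Camera called that list higher without untreated replicate 3 (adjusted p = 0.0153) and without a filter on low values (0.0294), within a range of 0.0153 to 0.445 over all alternatives. Fasn measured 16.6 ± 4.23 and 22.2 ± 3.65 FPKM, Scd1 39.4 ± 6.27 and 38.4 ± 1.43 FPKM, and Acaca 4.40 ± 1.29 and 5.17 ± 0.447 FPKM. Srebf1, Dgat2, Pnpla2 and Lipe had adjusted p-values of 0.276, 0.194, 0.0808 and 0.213. Of 20 fatty acid oxidation genes, Acot2, a mitochondrial thioesterase, rose 2.59-fold (1 up adjusted over the list alone; adjusted p = 0.127 in camera, and 0.0398 without untreated replicate 1, within a range of 0.0398 to 0.589 over all alternatives), while Cpt1a and Acadm had adjusted p-values of 0.0645 and 0.0867. In the cholesterol synthesis list Insig1 rose 1.81-fold and Sqle was 1.66-fold lower among 23 members (4 up and 2 down adjusted over the list alone; adjusted p = 0.431 in camera), and Hmgcs1 had adjusted p = 0.0594.

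Autophagy and lysosome genes were higher, with 10 of 29 members up and 1 down (13 and 1 adjusted over the list alone). Mcoln1, a lysosomal calcium channel gene on chromosome 8 at 3500457 to 3515232, rose from 79.0 ± 2.57 to 143 ± 1.88 FPKM (n = 3 per group, limma adjusted p = 0.00379), Sqstm1, an autophagy receptor, from 306 ± 34.8 to 611 ± 58.5 FPKM, and the protease gene Ctsd 1.73-fold. Wipi1 was the member that fell. The list had adjusted p = 6.73e-07 in camera, 0.00596 in fry and adjusted p = 0.211 with an estimated correlation. Of the NRF2 antioxidant list, 4 of 22 members rose and 1, Gstm1, fell (8 and 2 adjusted over the list alone), among them heme oxygenase Hmox1, up 1.61-fold, with Srxn1 up 1.48-fold and Abcc4 up 1.88-fold. It had adjusted p = 0.0024 in camera, 0.0502 in fry and adjusted p = 0.398 with an estimated correlation. The NF-kB list had 3 of 20 members up and 0 down (5 up adjusted over the list alone), namely Relb, Saa3 and Cxcl1, with Saa3 at 1255 ± 497 and 2837 ± 372 FPKM. Its adjusted p was 0.00729 in camera, 0.146 in fry and adjusted p = 0.442 with an estimated correlation. Immediate early genes fell in 10 of 21 and rose in 2 (11 and 2 adjusted over the list alone), with Jun 1.89-fold lower and Myc, a growth regulator, up 2.48-fold and Atf3 up 2.22-fold. They had adjusted p = 0.00375 in camera, 0.0083 in fry and adjusted p = 0.197 with an estimated correlation.

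Cytosolic ribosomal protein genes and nuclear-encoded respiratory chain genes were called by camera as higher, with adjusted p = 0.00615 and 0.0122, although none of 61 and none of 48 members passed singly, also when adjusted over the list alone. Both calls were lost with an estimated correlation (adjusted p = 0.747 for each) and in fry (0.556 and 0.578), and without untreated replicate 3 the medians were -0.0085 and -0.04 (adjusted p = 0.864 and 0.806, over all alternatives 2.79e-07 to 0.864 and 6.43e-06 to 0.806). Lists without a camera call were the tricarboxylic acid cycle (0 of 20 members, also adjusted over the list alone; adjusted p = 0.0954, but 0.0371 without untreated replicate 1 and 0.0121 without a filter on low values, within a range of 0.0121 to 0.349 over all alternatives), mitochondrially encoded respiratory genes (0 of 11, also adjusted over the list alone; 0.396, and 0.000269 without flavonoids replicate 3, within a range of 0.000269 to 0.985 over all alternatives), peroxisome (0 of 22, also adjusted over the list alone; 0.999) and AMPK and PGC-1 genes (1 of 16 down, Prkab2, also adjusted over the list alone; 0.753). Prkaa1 and Ppargc1a in that last list had limma adjusted p-values of 0.247 and 0.084. Among insulin signalling genes 1 of 29 rose, Trib3, and 3 fell, among them Slc2a1 and Foxo1 (also 1 and 3 adjusted over the list alone; camera adjusted p = 0.356, and 0.0202 without untreated replicate 1 with a median of -0.23, within a range of 0.0202 to 0.956 over all alternatives), while Insr and Irs1 had adjusted p-values of 0.693 and 0.415. Among adipokines 1 of 10 rose, Agt, and 3 fell, among them Rarres2, 2.41-fold lower, and Apln, 1.63-fold lower (2 up and 3 down adjusted over the list alone; camera adjusted p = 0.716). The adipokine and peroxisome medians were 0.0098 and 0.0048, while their means, -0.10 and -0.03, and the tests pointed down. Branched-chain amino acid genes Bcat1, Bcat2 and Bckdha rose among 18 (3 also adjusted over the list alone; camera adjusted p = 0.218). Aldh3a1 and Ahr fell among 11 xenobiotic response genes, also adjusted over the list alone, with camera adjusted p = 0.315, fry 0.0363 and adjusted p = 0.555 with an estimated correlation.

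Among 19 p53 targets 5 rose, with Gadd45a up 2.53-fold and Sesn2 up 1.98-fold, and 2 fell, with Sesn1 1.91-fold lower (6 up and 4 down adjusted over the list alone; camera adjusted p = 0.504). Cytosolic heat shock genes gave 1 up, Hspe1, and 1 down, Dnajb4, among 14 (3 and 1 adjusted over the list alone; 0.462), circadian genes 2 up, Bhlhe40 and Cry1, among 15 (2 up adjusted over the list alone; 0.206), glucocorticoid targets Mt2 up and Dusp1 down among 15 (3 and 1 adjusted over the list alone; 0.431) and complement genes Saa3 up among 11 (3 up and 1 down adjusted over the list alone; 0.218, with fry 0.0425 and adjusted p = 0.442 with an estimated correlation). The thermogenic, histone, macrophage, endothelial, skeletal muscle and bone and cartilage lists had fewer than 5 tested members and were not tested as lists. Of the 57 macrophage, endothelial, muscle, bone and cartilage markers in the table, 9 were tested, of which Cd14 was higher (log2 change 0.86) and Egfl7 lower (log2 change -0.88) with flavonoids.

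The list test with the preset correlation may be permissive in these data. It called 16 lists, 8 higher and 8 lower, and 0 remained with an estimated correlation, but it also called between 8 and 14 lists in the other 9 divisions of the 6 libraries into 3 and 3. Fry called 13 lists in the real division and 0 in each of those 9. Those 9 mix treated and untreated libraries on both sides. They keep part of the group difference and also add it to the spread within sides. They are therefore no clean measure of false calls for either test. The first principal component held 52.4% of the variance and separated the groups, with untreated libraries at -32.5, -18.0 and -5.34 and treated ones at 12.5, 15.0 and 28.3, while the second, with 25.6%, spread the untreated libraries. Untreated libraries also differed in their trend over gene length, with slopes of -0.116, 0.0169 and 0.159 log2 units per doubling of length against -0.0123, -0.0174 and -0.0303 in treated ones. The number of changed genes depended on single libraries, with 140 calls without untreated replicate 2 and 213, 360 and 516 without flavonoids replicate 1, 2 and 3. In simulated data of this size 98.0% of 2-fold and 58.2% of 1.5-fold changes were recovered and 9.53% of calls were false, above the nominal 5%. The simulation had the same dispersion for every gene and no trend over gene length, so these shares may not hold for the real libraries. On chromosome 17 between 33685692 and 40935047, 12 list members had means below 1 FPKM. Of the 189 protein-coding genes there other than olfactory receptors 3.70% reached it, so a low value there is not evidence of low expression.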

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

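The settings that remove the trend over gene length and the voom fit were chosen after seeing the data, and the others were planned. None of the 1145 called genes changed sign in any setting. Counts of higher and lower genes were 220 and 237 with the replicate block, 317 and 324 without a filter on low values, 1379 and 1131 with the length trend removed, 1106 and 911 with it removed and the block, and 1465 and 1640 at an unadjusted p under 0.05. No pairing by replicate number was seen, since same-number deviations correlated at -0.143, -0.117 and -0.203, against -0.0854 to 0.169 for different numbers. With 3 samples per group this cannot exclude a pairing. At least 2-fold changes numbered 97 higher and 209 lower with a pseudocount of 0.1, 29 and 26 with 5, and 105 and 230 with voom, and the lower ones numbered 74 without a filter, 63 at a mean of at least 5 FPKM, where fewer genes are tested, and 177 on the TPM scale. Removing the length trend kept 1137 of the 1145 calls and voom kept 1070. Leaving out 1 library gave 64 to 875 higher and 76 to 827 lower genes, and 46 to 84 higher and 60 to 146 lower at 2-fold. Totals were 140 without untreated replicate 2, 213, 360 and 516 without flavonoids replicates 1, 2 and 3, and 1702 without untreated replicate 1. With the length trend removed too, 1239, 692 and 1053 were higher and 1010, 601 and 889 lower without untreated replicates 1, 2 and 3, and 977, 1003 and 1273 higher and 805, 908 and 1246 lower without flavonoids replicates 1, 2 and 3. The share of variance on the first component ran from 52.4% to 65.7% with 1 library left out, was 58.5% with the length trend removed, and with both was 65.2%, 58.0% and 61.6% without untreated and 61.6%, 61.1% and 61.8% without flavonoids replicates 1, 2 and 3. Where no cause is named, the cause was not tested.

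Lists called higher and lower numbered 0 and 0 with an estimated correlation, and fry called 5 higher. Over the other settings camera called 6 to 11 higher and 7 to 9 lower. The direction of a list is that of its camera test, which can differ from the sign of its median, and the medians are given here. The directions that turned were those of results past no threshold in either setting, apart from nuclear-encoded respiratory genes, called with all libraries. Ribosomal protein genes, also called with all libraries, had a median of -0.0085 without untreated replicate 3, where the test still pointed higher. The nuclear-encoded respiratory median ran from -0.0405 to 0.272 with 1 library left out. Scd1 had a log2 change of 0.0589 with the length trend removed, with or without the block, ran from -0.154 to 0.0709 with 1 library left out, and with both was 0.0054, 0.0922 and 0.0737 without untreated replicates 1, 2 and 3 and 0.0889 and 0.102 without flavonoids replicates 1 and 2. Insr ran from -0.439 to 0.0820 with 1 library left out, and with the trend removed too was 0.0165, 0.0629 and 0.0255 without untreated replicates 2 and 3 and flavonoids replicate 3. The peroxisome test pointed lower with a median of 0.0048 with all libraries, and higher with a median of 0.0067 at pseudocount 0.1, 0.0011 at pseudocount 5, 6.0e-05 without a filter, 0.0383 at a mean of at least 5 FPKM, 0.0176 with quantile normalization and 0.0019 with the length trend removed. The median ran from -0.0875 to 0.0412 with 1 library left out, and with the trend removed too was 0.0607, 0.0219 and 0.0655 without untreated replicates 1 and 2 and flavonoids replicate 1. Without a filter the AMPK and PGC-1 and adipokine tests turned higher, with medians of 0.0077 and 0.0305 against -0.0169 and 0.0098 with all libraries and the filter, and with the trend removed the first was 0.0293 without untreated replicate 1 and the second 0.0983 without flavonoids replicate 3. The insulin signalling median ran from -0.233 to 0.0340 with 1 library left out. The mitochondrially encoded median ran from -0.0971 to 0.501, and with the trend removed was -0.0972 and -0.0283 without untreated replicates 1 and 2, -0.112 and -0.0663 without flavonoids replicates 1 and 2, and 0.445 without flavonoids replicate 3, where the list was called. The causes of these turns were not tested. Of 2038 comparisons over the 82 called named genes, 203 lost the call, 149 of them with a library left out, and 0 changed direction. Calls lost most often were those of Cry1 (12 of 24 other settings), Dusp1 (8 of 25) and Prkab2 (8 of 24). Cebpb lost its call in 6 of 25 and Ddit3 in 0 of 25. Depth limits the genes that rest on few fragments, such as TrnW with 1 to 15, G0s2 with 17 to 83 and Cda with 21 to 119 per library, and the share of genes called was 8.97% in the set with the fewest fragments and 11.9% in the set with the most.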

Other observations

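The tests below on other divisions of the libraries, gene length, counting error, neighbouring genes, levels of the cell identity lists and markers of other cell types were chosen after the result was seen, as were the gene groups and the stretch of chromosome described first. Genes of ribosome biogenesis were higher with flavonoids, with 12 of 24 tested members up and 0 down. Rrp12 rose from 1.75 ± 0.233 to 5.87 ± 0.836 FPKM and the ribosomal RNA methyltransferase genes Nop2 and Fbl had log2 changes of 1.09 and 0.71. Cytosolic aminoacyl-tRNA synthetases, which charge transfer RNAs with amino acids, were up in 9 of 19 and down in 0, among them Aars (0.98), Wars (1.18) and Sars (0.85). Subunits of the vacuolar ATPase, the proton pump of lysosomes, were up in 7 of 16 and down in 0, with Atp6v0b at 0.89. Small leucine-rich proteoglycans, which bind collagen, were down in 6 of 8 and up in 0, with Aspn at -1.48, Ogn at -1.37, Podnl1 at -1.30 and Dcn at -1.12 beside Lum and Fmod. Because these 4 groups were picked from the called genes, their counts are descriptions and not tests. The iron importer genes Tfrc and Slc11a2 (log2 changes 1.08 and 1.33) and the caveolin genes Cav1 and Cav2 (-1.31 and -1.28), also chosen after their values were seen, changed in pairs.

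A stretch of chromosome 17 from 33685692 to 40935047 (GRCm38), around Vars and including the major histocompatibility complex, was almost empty in this table. Of its 189 protein-coding genes other than olfactory receptors 7 reached a mean of 1 FPKM, which is 3.70%. Of these 189 genes 108 were listed at 0 in all 6 libraries. Over the genome 47.5% of 20638 protein-coding genes reached a mean of 1 FPKM, a share taken with olfactory receptors included. The stretch was chosen after its values were seen and it was extended on each side until the second gene of at least 5 FPKM. It holds genes that every cell uses, such as Vars, Rps18 and Rps28, and 12 members of the fixed lists, Agpat1, Aif1, Angptl4, C4b, Cfb, Hspa1a, Hspa1b, Ier3, Neu1, Rps18, Rps28 and Tnf. All 12 had a mean under 1 FPKM and were not tested, so their response was not assessed. Neu1 came near the filter, at 0.731 to 0.942 FPKM in untreated and 1.11 to 1.13 FPKM in treated libraries. In each library between 6 and 11 of the 189 genes reached 1 FPKM.

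The first pattern is the difference between the groups, where the real division called 1145 genes and the highest of the 9 others called 1, for 2-fold changes 173 against 1, and for lists 16 against 14. Of the 10 divisions, 1, the real one, reached each real count, and 10 divisions are too few for a share under 0.05. The 9 others mix both groups, so the group difference widens the spread within their sides. Low gene counts there were thus partly fixed in advance. The trend over gene length is argued against as the whole cause, since 99.3% of the calls stayed in the same direction with it removed. Counting error alone is argued against. For 99.1% of the called genes the summed fragments of the groups differed beyond it (two-sided exact test, Bonferroni threshold over the 11464 genes). That test leaves out the spread between samples, which also exceeded counting error within groups (chi-square per degree of freedom 6.12 to 112). It was run on called genes only, so noise between samples stays open. The share called among the genes with the fewest fragments differed from that of the others by -1.36 percentage points (8.97% against 10.3%, 95% interval -2.59 to -0.133, genes taken as independent). That difference alone decides nothing, since noise also widens the spread within groups. An effect of the treatment remains an open hypothesis, as does any unrecorded difference in how the 2 sets of cultures were handled, which the design cannot separate from it.

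The second pattern is that 12 of 25 mature adipocyte genes lay under 1 FPKM in cells labelled adipocytes. The median share of exonic sequence these genes have in common with another gene was 0%. Fragments lost to gene copies are argued against for those at or near 0% (Plin1 at 0.194%). The explanation stays open for Adrb3, Gpd1 and Aqp7, which shared 24.9%, 12.97% and 3.87%. Gapdh, which every cell uses, was at 6.01 FPKM with 25.1% shared. The ribosomal protein gene Rpl34 was at 14.5 FPKM with 7.78% shared, but Rps14 at 2442 FPKM with 8.52%. Where some sequence is shared, the test therefore cannot decide. Because Vars is listed at 0 with 0% shared sequence, that test alone would miss losses like those on chromosome 17, but a median of 55% of the 20 neighbouring genes of the 12 reached 1 FPKM, with 40% the lowest (Cd36), against 0%, 5%, 20% and 30% around Vars, Rps18, Rps28 and Angptl4 of that stretch. Too low a depth is argued against, since 3 fragments were worth a median of 0.0472 FPKM. A candidate explanation is that many cells lacked the mature programme: in 6 of 6 libraries the median of the preadipocyte and fibroblast list exceeded that of the mature adipocyte list, but levels of different genes have no common scale and no undifferentiated sample was analysed here, so this stays open.

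The third pattern is the rise of stress genes with the fall of hypoxia, glycolysis and interferon genes. The length trend is argued against here too, since 100% of the called members of these 4 lists stayed called with it removed. Cells of another type stay open: 1 of 9 tested macrophage, endothelial, muscle, bone and cartilage markers was higher, Cd14, but at most 3 were tested of any type, which is too few to decide. The most abundant tested macrophage, endothelial, muscle and bone or cartilage markers were Cd14, Egfl7, Des and Spp1, at 18.0, 2.38, 6.27 and 339 FPKM. Sox9, also a bone and cartilage marker, was at 50.7 FPKM. A hypothesis is that the activity of hypoxia-inducible factors may be lower in treated cells, and a second set of 17 hypoxia genes, written before its values were seen, had a median log2 change of -0.37 over 15 tested members, 3 of them called lower and 0 higher (Zfp395, Tmem45a and Plod1). Its camera p was 4.84e-05, a test that also fell under 0.05 in 4 of the 9 other divisions. Its fry p was 0.00122, against 0.383 or more in those divisions. They mix both groups, which widens the spread within their sides, so high fry p-values there were partly fixed in advance. The camera p of the set with an estimated correlation was 0.036. Neither oxygen nor the protein was measured, so the hypothesis stays open.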
